A study of Mus musculus with 6 samples.

How the data were processed

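The samples were 6 ChIP-seq libraries from LJE1, an immortalized mouse line derived from a non-small cell lung tumour that carried mutant Kras and lacked Lkb1. Per the labels, 2 H3K9ac libraries and 1 input library came from HDAC3 knockout (KO) cells, and 2 H3K9ac libraries and 1 input library came from control cells labelled NT. The groups were taken from the sample titles and genotypes; the free-text description of the NT samples names an Hdac3 guide, which conflicts with both, and the titles were used. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels describe formaldehyde crosslinking, sonication and immunoprecipitation from equal cell numbers, with no spike-in mentioned.

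The submitters' processing notes name STAR 2.4.0k, HOMER 5.1 and the mm10 build. The deposited data are a table of HDAC3 peaks and a table of mean H3K9ac signal around those peaks. Per the file headers, the peak table is a HOMER annotation of HDAC3 ChIP-seq peaks, called in NT cells against NT input and HDAC3 KO libraries, joined by gene to a differential RNA comparison of HDAC3 KO against NT cells. The HDAC3 ChIP-seq and RNA libraries behind it are not among the 6 samples. The table also has 6 columns of per-sample RNA values that match no sample here and were not used. Their headers do not name the line of the ChIP-seq libraries, so whether the RNA came from the same line is not shown. The deposited peak score and the deposited focus ratio, a fraction from 0 to 1, are the authors' own values per peak and served only to describe and rank peaks within the list. The log2 fold change of RNA, its p-value and its adjusted p-value are the authors' deposited values and were copied, not recomputed. One gene symbol had turned into a calendar date in the table and was restored as Septin7 from its gene identifier. All 200 genes matched the RefSeq table of the GRCm38.p6 assembly, which has the mm10 coordinates.

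Per the file headers, the deposited H3K9ac coverage and the tag density on each strand are HOMER averages over the 264 peaks in 161 bins of 25 bp, from -2000 to 2000 bp around the peak centre. The signal is normalized per library; the amount it is scaled to is not given in the sources used here. No value per peak or per gene was available in it, so H3K9ac could be compared only over the 264 peaks together. Every one of the 322 strand values of each library was a whole multiple of 1 step, within 1e-06 of a step. The step gives the scaling factor, rounded to 2 decimals: 0.47 and 0.54 for NT replicates 1 and 2, and 0.31 and 0.09 for KO replicates 1 and 2. Rounding leaves each library's level uncertain by up to 1.06%, 0.926%, 1.61% and 5.56%, in the same order. The coverage values were whole numbers of fragments, within 0.0001, at fragment lengths of 155, 352, 439 and 203 bp, again in that order.

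The planned analysis assumed H3K9ac peak lists. As the table holds normalized signal, the test planned for normalized values was used: limma 3.58.1 in R 4.3.3 on log2(coverage + 1) per bin, 2 KO against 2 NT libraries, with no replicate block and Benjamini-Hochberg adjustment over the 161 bins at 0.05. Log2 differences are therefore on the log2(value + 1) scale, which understates changes in low bins. No bin was filtered. Neighbouring bins share fragments, so the adjusted p-values treat the bins as more independent than they are. In both measures limma pooled the variance fully over bins, giving every bin the same standard error, so its p-values rest on the spread over all bins of 4 libraries and not on each bin's own replicates; they are smaller than 4 libraries alone allow. On simulated data with 50 of the 161 bins changed, the coverage test recovered 21.0% of bins changed 1.1-fold and 92.8% of bins changed 1.25-fold, and the tag test 58.8% and 94.2%. The simulated bins varied independently of each other, unlike real ones. After the data were seen, the tags of both strands per 100 bp were tested in the same way, and means were taken over a centre (within 100 bp), shoulders (200 to 600 bp), a middle zone (700 to 1400 bp) and flanks (1500 bp and beyond). Zone means were compared by a two-sided exact permutation test, which cannot go below p = 0.333 with 2 libraries against 2.

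Shares of peaks have Wilson 95% intervals, which cover counting error only. A peak within 1000 bp of the transcription start site (TSS) of its assigned gene was counted as a promoter peak. The 18 gene lists were fixed before the data were examined, as were the tests, the main settings and those other settings not said to be added later; 478 of their 479 genes matched RefSeq. They cover chemokines, interferon response, antigen presentation by MHC class I and class II, NF-kB targets, secreted factors of senescent cells, lipid metabolism, cell cycle and p53, lung lineage, feedback of the MAPK pathway, epithelial-mesenchymal transition and matrix, the HDAC3-NCoR complex, AP-1 factors, germline genes, neuronal genes, housekeeping genes, and markers of lymphoid and myeloid cells and of stroma and endothelium. Each was tested with a two-sided Fisher's exact test against 21900 protein-coding genes, adjusted over the 18 lists. The genes that could have entered the table are those with an HDAC3 peak and measurable RNA; that background was not available, so these tests compare with all protein-coding genes. On 100 random sets of 200 protein-coding genes the test called 0 lists. With 5 or 10 lipid genes planted, it called the lipid list in 100% of runs and other lists 4 times per 100 runs. The sets were drawn evenly from the background itself. They cannot show the error rate for genes limited to those with an HDAC3 peak and measurable RNA. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

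The genes named are, by a rule set before the data were examined, Hdac3, the 12 genes with the largest values in the comparison, the 12 with the highest peak score, up to 4 members of each list by score, and all chemokines. The gene families in the closing part were chosen after their values were seen. Alternatives covered the pseudocount, the replicate block, leaving out each library, the scaling, the fragment length, the promoter distance and the background of the gene lists. The profiles of the input libraries were not analysed here.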

Results

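The data address whether loss of HDAC3, a histone deacetylase that acts in the NCoR corepressor complex, changes acetylation of histone H3 lysine 9 (H3K9ac, a mark of active promoters and enhancers) in Kras-mutant, Lkb1-null lung tumour cells. H3K9ac was profiled in 2 HDAC3 KO and 2 NT libraries around 264 HDAC3 peaks assigned to 200 genes. The windows of 4000 bp held 120955 and 104058 tags in NT replicates 1 and 2, and 196470 and 657807 tags in KO replicates 1 and 2. If HOMER's default scaling to 10000000 tags was used, which the headers do not state, the library totals in units of 1000000 tags were about 21.3 and 18.5 for NT and 32.3 and 111 for KO. Hdac3 itself is not among the 200 genes and the profiles do not separate genes, so the knockout could not be checked in the H3K9ac libraries.

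The first comparison asks which genes and regions the HDAC3 peaks mark. In the authors' deposited table, all 200 genes had higher RNA in HDAC3 KO than in NT cells, with log2 fold changes from 0.13 to 2.06 and adjusted p-values up to 0.0494. The peak numbers in the table run, summed over chromosomes, to at least 16517, so the 264 peaks are at most 1.60% of those numbered and were selected by the RNA of their genes. The table holds only genes with raised RNA, so the shared direction is a property of how it was put together and not independent evidence. Its changes were mostly small: the median in the authors' deposited table was 0.31 on the log2 scale, 108 genes changed less than 1.25-fold, 34 at least 1.5-fold and 14 at least 2-fold.

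The largest value in the authors' deposited table belonged to Ddit4l, a relative of the mTOR inhibitor Ddit4, with a log2 fold change of 2.06 (adjusted p = 3.57e-12). Its HDAC3 peak lay in an intergenic region 33137 bp upstream of the TSS, on chromosome 3 from 137590344 to 137590726 (mm10). Next in the authors' deposited table was Abca1, with a log2 fold change of 1.81 (adjusted p = 0.00129). Abcg1, like Abca1 a transporter that exports cholesterol, had 1.25 on the log2 scale in the authors' deposited table (adjusted p = 2.57e-09). The Abca1 peak was intergenic, on chromosome 4 from 53202679 to 53203061, and the Abcg1 peak lay in an intron, on chromosome 17 from 31067022 to 31067404. The rest of the 12 largest log2 fold changes in the authors' deposited table were Ccl5 (1.66), Dnah6, an axonemal dynein heavy chain (1.65), Sulf2, a heparan sulfate sulfatase (1.62), Plekhs1 (1.52), Zfp365 (1.497), Acot1, an acyl-CoA thioesterase (1.41), Aspa (1.27), Calcb (1.22) and Nupr1, a stress-induced chromatin protein (1.19). Of these 12 genes, Nupr1 alone had a peak within 1000 bp of its TSS.

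T cell recruitment is the subject of the series title, and 2 of 36 protein-coding chemokine genes had a listed peak. Ccl5, which attracts T cells through CCR5, had a log2 fold change of 1.66 in the authors' deposited table (adjusted p = 0.00125). Its peak was intergenic, 4334 bp upstream of the TSS, on chromosome 11 from 83534661 to 83535043. Cxcl10, an interferon-induced ligand of CXCR3, had a log2 fold change of 0.93 in the authors' deposited table (adjusted p = 0.0243). Its peak was at the promoter, 100 bp upstream of the TSS, on chromosome 5 from 92348798 to 92349180. No gene of the lists for MHC class I, MHC class II, AP-1 factors, germline genes, neuronal genes, lymphoid and myeloid markers, or stroma and endothelium had a listed peak, and of the 45 genes of the interferon response list Trim25 alone had one. The lists without a peak hold 11 to 34 protein-coding genes each, and 0.881% of all protein-coding genes had a listed peak. With lists this short, a count of 0 is near that share and is no result about their genes.

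Lipid metabolism had the smallest p among the lists, with 5 of 42 genes (11.9%, Fisher's exact adjusted p = 0.000593). The share among 21900 protein-coding genes was 0.881%, an odds ratio of 15.6. In the authors' deposited table their log2 fold changes were 1.81 for Abca1, 1.25 for Abcg1, 0.58 for Angptl4, a secreted lipase inhibitor, 0.56 for Plin2, a lipid droplet coat protein, and 0.29 for Scd2, a fatty acid desaturase. NF-kB targets had 4 of 38 genes (adjusted p = 0.00307): Vcam1, an adhesion molecule for leukocytes (log2 fold change of 0.93 in the authors' deposited table), Csf3 (0.69), Bcl2l1 (0.22) and Lif (0.19). Among secreted factors of senescent cells 4 of 46 were listed (adjusted p = 0.00429), namely Il33, with 0.96 on the log2 scale in the authors' deposited table, Ccl5, Csf3 and Serpine1 (0.32).

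Feedback genes of the MAPK pathway had 3 of 24 members (adjusted p = 0.00535), with log2 fold changes in the authors' deposited table of 0.78 for Ier3, 0.21 for Dusp5 and 0.19 for Epha2. Cell cycle and p53 genes had 3 of 27 (adjusted p = 0.00607), with 0.55 for Bbc3, 0.46 for Gadd45b and 0.28 for Cdkn2b on the log2 scale in the authors' deposited table. Lung lineage genes had 3 of 34 (adjusted p = 0.00989): Cebpd (0.74 on the log2 scale in the authors' deposited table), Krt18 (0.38) and Krt7 (0.15). Housekeeping genes also passed, with 2 of 20 (adjusted p = 0.0340), Rplp0 (0.33 on the log2 scale in the authors' deposited table) and Hprt (0.19), but 0 of 20 were listed when only peaks of above-median score were used. Against the 473 protein-coding genes of the 18 lists together, in place of all protein-coding genes, no list passed the Fisher test after adjustment (0 at an unadjusted p under 0.05), and the lipid odds ratio was 2.397 (adjusted p = 0.821). Matrix and mesenchymal genes (Tnc and Col4a2; adjusted p = 0.0725), chemokines (adjusted p = 0.0800), the HDAC3-NCoR complex (Tbl1xr1; adjusted p = 0.153) and the interferon response (adjusted p = 0.538) did not pass against all protein-coding genes. The chemokine list passed in the other settings planned: adjusted p = 0.0193 against all annotated genes, 0.0490 with peaks within 10000 bp of the TSS and 0.0394 with peaks of above-median score. With peaks within 10000 bp, NF-kB targets (adjusted p = 0.343), cell cycle and p53 genes (0.321) and lung lineage genes (0.343) no longer passed, and with peaks of above-median score the senescence factors did not (0.0538).

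The listed peaks, a selected part of the numbered HDAC3 peaks, were mostly away from promoters. The authors' annotation placed 135 of 264 peaks (51.1%, 95% interval 45.1% to 57.1%) in intergenic regions, 63 (23.9%, 19.12% to 29.4%) in introns and 57 (21.6%, 17.1% to 26.9%) at promoters. Within 1000 bp of the assigned TSS were 64 peaks (24.2%, 19.5% to 29.8%), within 10000 bp 120 (45.5%, 39.6% to 51.5%) and within 50000 bp 221 (83.7%, 78.8% to 87.7%). The authors assigned peaks to the nearest TSS, and 31 of 264 peaks lay closer to the body of another protein-coding gene. Most genes (151) had 1 peak, 39 had 2, and Myo10, an unconventional myosin, had 6, the most of any gene.

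The highest peak score was 177.2, at a peak assigned to Tmem252, followed by Trim25 (162.8), a ubiquitin ligase in antiviral signalling, the pseudogene Pisd-ps1 (154.4), Krt18 (144), Scd2 (139.9) and Pdk4, an inhibitor of pyruvate dehydrogenase (131.3). Thumpd3 (111.6), Prickle1 (111.3), Lpcat3 (108.4), Myo10 (108.1), Tns4 (104.1) and Denr (103.2) completed the 12 highest peak scores. Of these genes, Pdk4 alone reached 2-fold in the authors' deposited table, with a log2 fold change of 1.01, and the others ranged from 0.16 for Denr to 0.40 for Tns4.

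**Figure D1:**
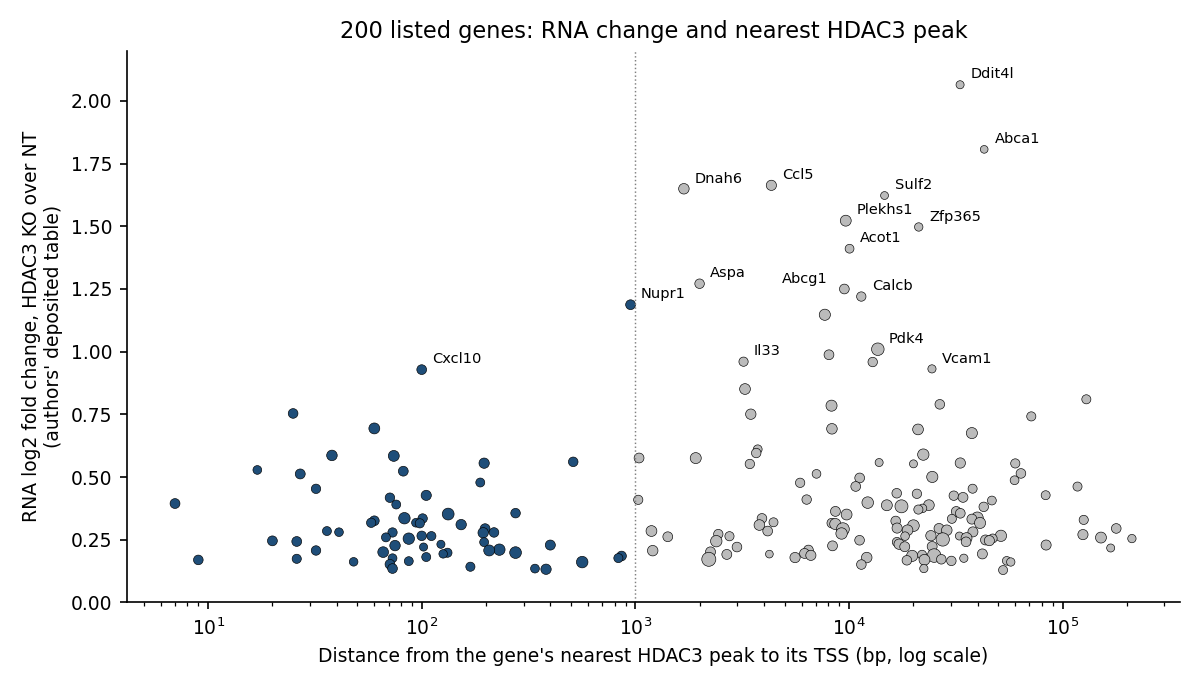
Each of the 200 points is a gene, placed by the distance from its nearest HDAC3 peak to its TSS (bp, log scale) and by its RNA log2 fold change in the authors' deposited table; point size grows with the peak score, and blue points have a peak within 1000 bp of the TSS (dotted line). The values run from 0.13 to 2.06, and Nupr1 (1.19) has the highest among the genes with a promoter peak.

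The second comparison asks whether H3K9ac around these HDAC3 peaks differed between HDAC3 KO and NT cells. At the peak centres H3K9ac coverage was 7.89 ± 0.646 (SD, n = 2) in KO and 7.996 ± 0.0475 (SD, n = 2) in NT, a ratio of 0.987 that was within the spread between replicates. Shoulder coverage, the highest of the 4 zones, was 9.77 ± 0.588 (SD, n = 2) in KO and 9.89 ± 0.844 (SD, n = 2) in NT, also within the spread. In tags, however, both KO libraries lay above both NT libraries at the shoulders (8.76 ± 0.123 against 8.55 ± 0.111, SD, n = 2 each). Coverage rebuilt from the tags at 1 fragment length also had KO higher there (9.18 ± 0.154 against 8.95 ± 0.125). At the centre the rebuilt KO libraries both lay below NT (6.70 ± 0.130 against 6.87 ± 0.0287). These differences were 2.55% in shoulder tags, 2.52% in rebuilt shoulders and -2.55% at the rebuilt centre. Rounding leaves the level of KO replicate 2 uncertain by up to 5.56%, which is more, so the order of the libraries stays open there. Farther out in deposited coverage the KO libraries were above both NT libraries: by 7.83% in the middle zone (5.62 ± 0.0693 against 5.21 ± 0.314, SD, n = 2 each) and by 11.2% in the flanks (3.25 ± 0.0656 against 2.92 ± 0.166, SD, n = 2 each). In the middle zone KO replicate 2 (5.66) and NT replicate 1 (5.43) lay closer than that rounding allows, so their order is open too. For the middle zone and the flanks the exact permutation p was 0.333, the smallest this design allows, so no zone could pass 0.05.

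All 4 libraries showed H3K9ac on both sides of the HDAC3 peak with a dip between. Coverage in NT replicate 1 peaked at 11.9 at -275 bp and 11.3 at 350 bp and was 7.62 at the centre. KO replicate 1 reached 9.79 at -350 bp and 9.63 at 400 bp, with 8.26 at the centre. The other replicates went the other way: NT replicate 2 reached 9.84 with 7.78 at the centre, and KO replicate 2 reached 11.4 with 6.99. In tags the left maxima were 9.61 and 9.66 in NT replicates 1 and 2, and 9.79 and 9.59 in KO replicates 1 and 2. Replicates of a group differed in this shape, with shoulder coverage 12.8% apart between the NT libraries and 8.89% apart between the KO libraries.

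**Figure D2:**
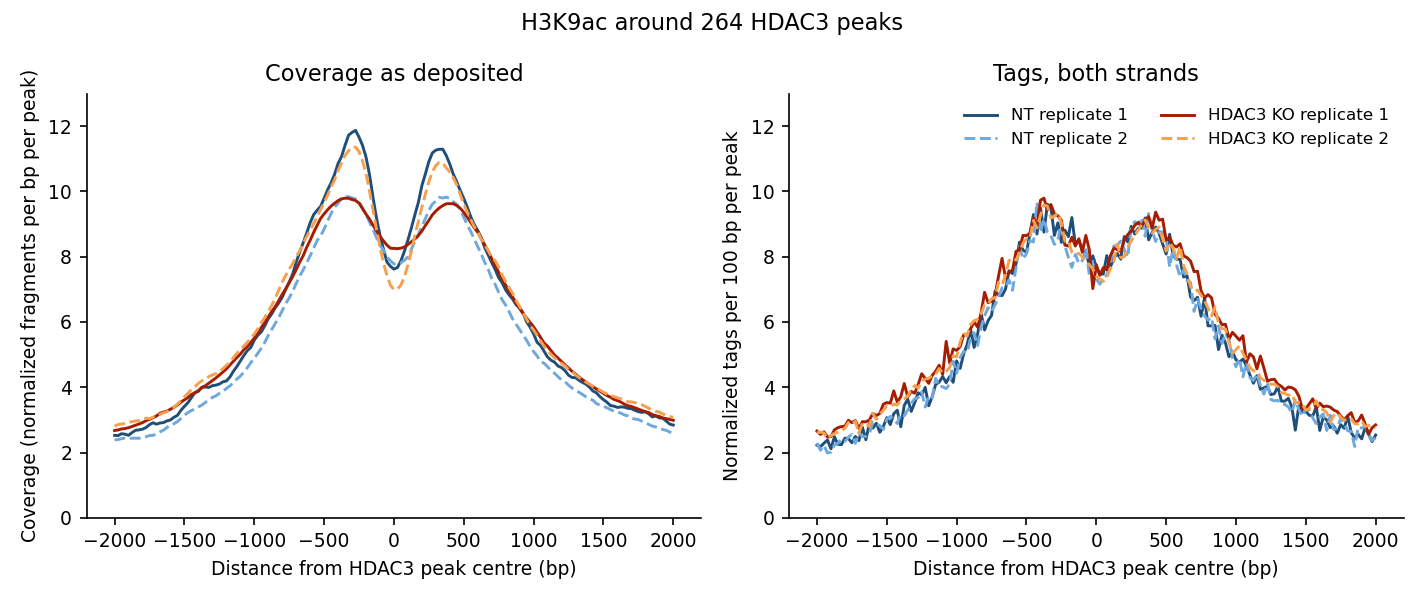
Mean H3K9ac around 264 HDAC3 peaks in the 4 libraries against distance from the peak centre (bp), as deposited coverage (left, normalized fragments per bp per peak) and as tags of both strands (right, normalized tags per 100 bp per peak). In coverage NT replicate 1 (maximum 11.9) and KO replicate 2 (maximum 11.4) have the highest shoulders, while in tags the 4 shoulders lie close together.

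In the per-bin test, limma called 0 of 161 coverage bins between KO and NT, with 14 at an unadjusted p under 0.05 and a smallest adjusted p of 0.434. The log2 difference was above 0 in 123 bins, and ranged from -0.06 to 0.15 over all bins. The deposited coverage level also depended on fragment length, which differed between libraries, so this test is not free of that offset. Over the whole window, KO over NT coverage was 1.04. It was 1.09 without NT replicate 1 and 0.991 without NT replicate 2, and 1.05 and 1.02 without KO replicates 1 and 2. Fits without 1 library leave 1 in a group, so they cannot show that the count of bins is stable. Other treatments of coverage, added after the data were seen, gave other limma counts. Rebuilt at 1 fragment length, it gave 98 of 147 bins, all higher in KO. The rebuilt coverage comes from the tags and keeps their rounded scaling factors. Its count was not tried at other factors for KO replicate 2 or after division by the window mean. In the deposited coverage, division by each library's window mean gave 26 of 161 (24 higher, 2 lower), and crossed pairing of the replicates gave 46. Tag density, which involves no extension of tags to a fragment length, gave another count: 54 of 161 bins were higher in KO and 0 lower (limma, Benjamini-Hochberg adjusted p under 0.05). This measure was chosen after the data were seen.

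The bins called in tags lay in the outer part of the window, 26 of 58 in the middle zone and 24 of 42 in the flanks, and none lay within 600 bp of the centre. The largest log2 difference in tags was 0.24 ± 0.05 (SE, pooled over all bins and so the same in each) at 1850 bp, from 2.31 tags per 100 bp in NT to 2.90 in KO (limma adjusted p = 0.000587). The next, 1075 bp to the other side of the centre, was 0.23 ± 0.05 (SE), from 4.05 to 4.95 tags per 100 bp (limma adjusted p = 0.000587). Flank density was 2.998 ± 0.0565 tags per 100 bp (SD, n = 2) in KO and 2.65 ± 0.00330 (SD, n = 2) in NT, while at the centre it was 7.70 ± 0.184 (SD, n = 2) in KO and 7.72 ± 0.144 (SD, n = 2) in NT. Without KO replicate 1 no bin was called, and without KO replicate 2 the count was 17. In these fits the lone KO library is assumed to vary like the NT libraries. No tag bin was called when KO replicate 2 took the lowest scaling factor that rounds to its own (83 at the highest), or when each library was divided by its own window mean.

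The ratio of centre to flank density, in which a scaling factor cancels, was lower in both KO libraries. It was 2.96 and 2.88 in NT replicates 1 and 2 and 2.58 and 2.56 in KO replicates 1 and 2 in tags (exact permutation p = 0.333). In coverage the ratio was 2.43 ± 0.248 (SD, n = 2) in KO and 2.74 ± 0.140 (SD, n = 2) in NT. The groups did not overlap, but NT replicate 1 (2.64) and KO replicate 1 (2.61) were nearer each other than the replicates of either group. Replicate 2 had 2.84 in NT and 2.26 in KO. Signal scaled to the library total cannot show a change shared by the whole genome, and nothing in these averages tells which of the 264 peaks contributed.

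**Figure D3:**
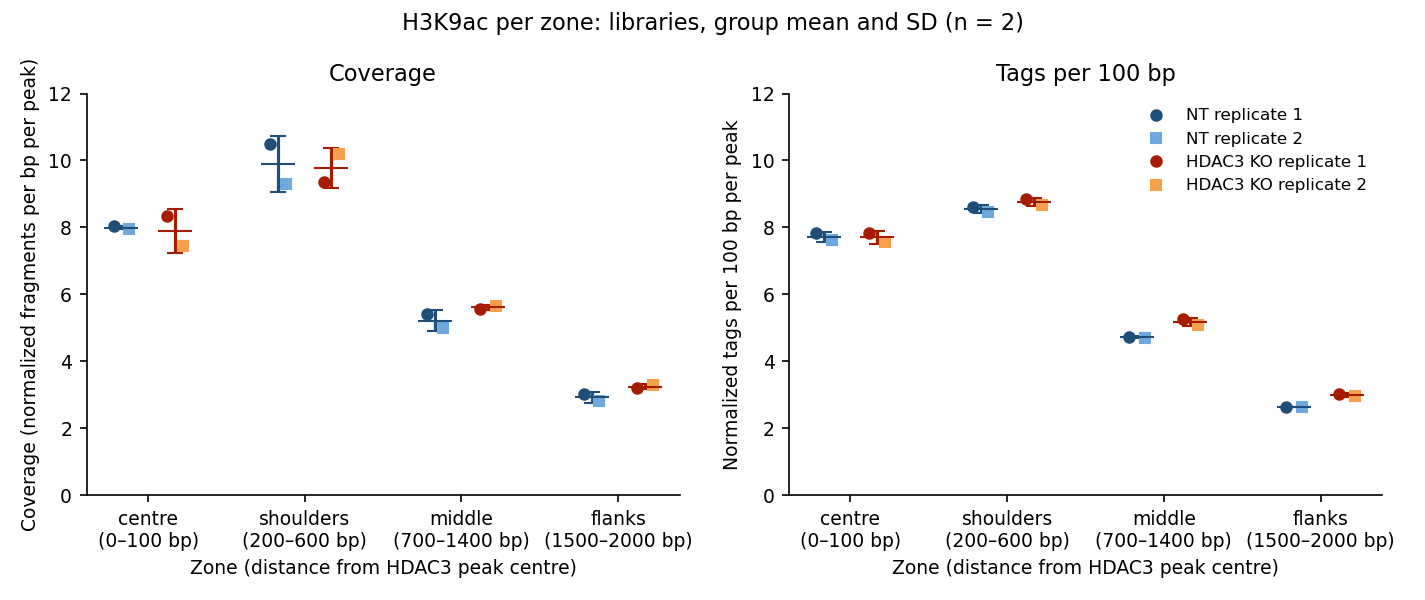
H3K9ac per zone as deposited coverage (left, normalized fragments per bp per peak) and as tags (right, normalized tags per 100 bp per peak); points are libraries and bars are the group mean and SD (n = 2). At the centre the groups overlap in both measures, and in the flanks both KO libraries (3.04 and 2.96 tags per 100 bp) lie above both NT libraries (2.65 and 2.64).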

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

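The zones and the measure, scaling and pairing alternatives below were chosen after the data were seen, and those on pseudocount, block, left-out libraries, fold limits, promoter distance and list background were planned, except the background of list genes; for tags and zones every alternative was added. Coverage calls stayed at 0 under pseudocounts of 0.1 and 5, with each library left out in turn (0 to 0), under both fold limits, and at both ends of the rounding of KO replicate 2. With the replicate number as a block, coverage again gave 0 bins and tags 45. Same-numbered libraries did not deviate together (correlation over bins -0.80 in coverage and -0.10 in tags); with crossed pairing coverage gave 46 bins and tags 53. Coverage rebuilt at 1 fragment length of 200 bp gave 98 of 147 bins, all higher in KO (the outermost bins cannot be rebuilt), and coverage divided by each library's own window mean gave 26, of which 24 were higher and 2 lower. In tags, where 54 bins were called, leaving out 1 library gave 0 to 59 (0 without KO replicate 1, 17 without KO replicate 2, the lone library being assumed to vary like the other group), a limit of 1.5-fold or 4-fold gave 0, the lowest and highest factors for KO replicate 2 gave 0 and 83, and division by the window mean gave 0. Rounding of that factor therefore limits the tag calls. The 98 bins of rebuilt coverage come from the same tags and factors, so they are open to the same limit. That coverage was not run at the lowest or highest factor, or after division by the window mean. The causes of the other changes were not tested, apart from the fragment length below. Zone ratios of KO over NT moved by less than the spread between replicates in all settings. For left-out libraries this was fixed in advance, as dropping 1 of 2 libraries moves a group mean by less than their SD. It therefore shows no robustness there. Without 1 library the flank ratio ran from 1.07 to 1.16 and the centre-to-flank ratio from 0.823 to 0.951. The promoter share stayed inside its interval, from 21.6% to 29.5%, with 263 autosomal peaks and with 129 peaks of above-median score. Lists called numbered 7, and 9 against all annotated genes, 5 with peaks within 10000 bp, 6 with the top-scoring peaks and 0 against list genes only. That last background had fewer genes, and 28 of its 473 (5.92%) were listed, against 0.881% of all protein-coding genes. The lipid odds ratio there was 2.397, against 15.6. Against all annotated genes, matrix and mesenchymal genes (adjusted p = 0.0164) and chemokines (0.0193) were added. With peaks within 10000 bp, NF-kB targets (0.343), cell cycle and p53 (0.321) and lung lineage (0.343) lost their call and chemokines (0.0490) gained one; with the top-scoring peaks, senescence factors (0.0538) and housekeeping genes (0 of 20, adjusted p = 1) lost theirs and chemokines (0.0394) gained one. These settings use fewer peaks. Not run were DESeq2 (left out because the deposited unit is a normalized signal, although whole tags per bin were recovered), library-size scaling as an alternative to TMM (TMM was not used), overlap of peak lists and a background of genes with an H3K9ac peak (no H3K9ac peaks), a fold over input (no such column), camera (no values per gene), a filter (it would remove no bin) and an annotation from the reference (it has no strand).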

Other observations

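Apart from the lipid list against all protein-coding genes and its setting by peak score, the tests in this part were chosen after the data were seen; the outcomes of the tests of open-chromatin background, gene families, peak position and peak score were not known when their predictions were written. Among the 200 genes were 3 of 11 aquaporins, water and glycerol channels: in the authors' deposited table Aqp3 had a log2 fold change of 0.60, Aqp8 of 0.51 and Aqp5 of 0.48. Semaphorins had 3 of 20 genes, with 0.45 for Sema3e, 0.22 for Sema3c and 0.20 for Sema4b on the log2 scale in the authors' deposited table. These families were picked by their counts, and over the 1423 symbol families with 3 or more genes the smallest adjusted Fisher p was 0.150, for aquaporins (odds ratio 42.8), so neither passed.

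A hypothesis on peak position was that genes with a promoter peak differ in RNA change from genes with distal peaks. In the authors' deposited table the mean log2 fold change was 0.33 for the 64 genes with a peak within 1000 bp of the TSS and 0.48 for the other 136 (permutation p = 0.00347 over genes, adjusted 0.00520 over 3 comparisons). The medians, 0.27 and 0.33 on the log2 scale in the authors' deposited table, gave a permutation p of 0.0509, which does not pass. Over other promoter distances and both statistics p ran from 0.00272 to 0.0966. Genes are not replicates, and all had been selected for raised RNA. Promoter peaks also had a lower focus ratio, with a median of 0.656 against 0.722 (permutation p = 1e-05 over peaks, the smallest the resamples can give), while the peak scores had medians of 54.4 and 57.5 (permutation p = 0.288). No relation between peak score and RNA change was detected: across genes, which are not independent replicates, Spearman's rho was 0.0130 (permutation p = 0.855, adjusted 0.855) and Pearson's r was -0.09 (permutation p = 0.183, adjusted 0.366) in the authors' deposited table, and without the 2 genes of most extreme score rho was 0.0356 and r -0.07. By the prediction written beforehand, a rho above 0 that does not pass decides neither way.

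Shoulder coverage differed between replicates of a group, by 12.8% between the NT libraries. Fragment length is a candidate explanation, since the lengths recovered from the coverage were 155 and 352 bp in NT and 439 and 203 bp in KO. Rebuilt from the tags at 1 length of 200 bp, the NT gap was 1.99%. The ratio of shoulders to centre, in which a scaling factor cancels, was compared as well. In deposited coverage it was 11.9% apart between the NT libraries and 22.3% between the KO libraries. Rebuilt at 1 length, these gaps were 1.39% and 0.369%. Setting 1 fragment length thus removed most of the difference between replicates in both groups. In deposited coverage the highest shoulders belonged to the libraries with the shortest fragments in each group. No biological explanation was tested, as replicates of a group share their labels.

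The centre-to-flank ratio of tags was lower in both KO libraries, and flank density was higher. Rounding of the scaling factors cancels in the ratio, so it could not alter the ratio whatever the values were. The nearest NT and KO ratios were 0.305 apart, against at most 0.0720 between replicates, which is no test of rounding. For the level over the whole window, rounding allows KO replicate 1 no less than 5.64 tags per 100 bp, above the highest NT value of 5.41, but KO replicate 2 as little as 5.26, which leaves its level open. Depth is argued against by the KO libraries, with 196470 and 657807 tags in the windows, whose ratios were 0.0182 apart, and an even background over the genome, if the profiles were scaled to 10000000 tags, by flanks that stayed at or above 2.79 tags per 100 bp in KO under any rounding, where it would have to bring them below NT (at most 2.68). A background that follows open chromatin cannot be told apart from a wider H3K9ac domain: the middle zone lay 1.95% and 2.302% above a straight line in NT density, the input profiles were not analysed here, and at the same scaling such a background would need to exceed an NT flank density that is 7.20 times an even spread. An effect of HDAC3 loss itself stays open and was not tested apart from these explanations.

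The lipid metabolism list held more listed genes than the protein-coding background (odds ratio 15.6). A candidate explanation is that the background counts genes that these cells do not express. Against housekeeping genes, which most cells express, the lipid odds ratio was 1.22 (95% interval 0.177 to 13.9, Fisher's exact p = 1), from 5 of 42 and 2 of 20 genes, an interval too wide to decide, and with peaks of above-median score the housekeeping count was 0. The background of all list genes, which gave an odds ratio of 2.397, still holds neuronal, germline and immune genes and does not test this. No biological explanation was tested, and both readings stay open. Among the listed genes, 6 lists had 3 or more members, and the medians of their log2 fold changes in the authors' deposited table had percentiles, among 10000 random lists of the same size and not adjusted for the number of lists, of 98.3 for senescence-associated factors, 95.7 for lipid metabolism, 82.9 for NF-kB targets, 82.0 for cell cycle and p53, 69.6 for lung lineage and 12.2 for MAPK feedback.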
